A study of Mus musculus with 16 samples.

How the data were processed

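Gene expression was measured in 16 samples of mouse bone marrow cells with Illumina mouse Ref-8 BeadChips, which read 1 colour from biotin-labelled copies of total RNA. Bone marrow cells carrying c-Kit, the stem cell factor receptor found on blood progenitors, came from 8-week-old wild-type C57Bl/6 and Booreana mice. They were transduced with a retrovirus carrying green fluorescent protein alone (control vector) or together with AML1-ETO9a, and sorted for green fluorescence and c-Kit 48 hours later, per the labels' protocols. The 4 groups, wild-type control, wild-type AML1-ETO9a, Booreana control and Booreana AML1-ETO9a, held 4 arrays each, assigned from the labels. The labels named 4 Booreana mice and gave no number of wild-type mice, and they did not say whether equal replicate numbers meant 1 animal, so p-values measure the spread between these arrays.

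Per the file headers, the deposited table held a non-normalized signal intensity and a detection p-value for each of 25697 probes on each array. Its lowest intensity was 112, so the array background had not been subtracted, and the detection p-values moved in steps that 798 negative control probes would give. The software behind these values is not given in the sources used here. A second deposited table held the authors' processed values on a log2-like scale, with the same median of 8.34 on every array and a range from 7.99 to 16.1. The submitters' processing notes name lumi, with no version or settings, so the exact transformation of that table stayed unknown. Each column of it matched the intensities of its own array best (16 of 16 arrays, lowest correlation 0.990). It was used as an alternative only.

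Intensities were corrected for background with limma's normexp method, with the negative probes' mean and spread inferred from the detection p-values and an offset of 16 added. They were then quantile normalized and put on the log2 scale (limma 3.58.1 with statmod 1.5.0 in R 4.3.3). Probes with a detection p under 0.05 on at least 4 arrays were tested, which left 12760 probes, of which 12015 carried a gene symbol, for 8833 genes. Gene names came from the platform's annotation table, which gave 1 symbol for 23978 of the 25697 probes, several for 0 and none for 1719; matching through gene identifiers updated 0 symbols. For a gene with several probes, the one with the highest mean over the 16 arrays stood for the gene, and other probes that disagree on a call are given beside it. A probe not detected on any array of a group has only a bound there, so its change is given as at least N-fold: the bright group's mean against, per array, the higher of the probe's own value and the lowest signal among detected probes. Where only some arrays of a group detect a probe, its fitted change is given, and its size rests partly on background.

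All arrays entered a limma model with 4 group means, and 5 comparisons were taken from it: AML1-ETO9a minus control in each genotype, Booreana minus wild-type with each vector, and the difference between the 2 responses to AML1-ETO9a. Adjusted p-values are limma's, by the Benjamini-Hochberg method over all 12760 probes, and a probe was called at an adjusted p under 0.05. Values after ± are standard errors of the fit unless SD is written. The size of the Booreana response was set against the wild-type response over 36 ways of choosing 200 probes on 4 of the wild-type arrays and measuring them on the others. The number of arrays limits the precision of every value.

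The 29 gene lists comprised cell type markers (early progenitors, neutrophil primary and late granules, monocytes, erythroid cells, megakaryocytes, mast cells and basophils, eosinophils, B cells, T and NK cells, dendritic cells with MHC class II, stroma), genes that earlier work ties to c-Myb or AML1-ETO, hematopoietic transcription factors, cytokine receptors, and pathways from DNA repair and the cell cycle to cholesterol synthesis. Each was tested with limma's fry, adjusted over the 29 lists within a comparison, with 1 probe per gene. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Of 145 pairs of list and comparison, 43 passed. With camera, which does compare with other genes, 34 of the 43 passed at its preset correlation of 0.01 and 8 passed with an estimated correlation.

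The groups, comparisons, lists and the rule for named genes were set before the data were examined, as were the alternatives listed below. Tests and alternatives added later are named as such where they are given. The rule took, per comparison, up to 12 largest rises and 12 largest falls among called genes whose 4 arrays against 4 did not overlap, leaving out clones and predicted genes. To these it added up to 4 members of each described list with the smallest adjusted p, and a fixed set of genes tied to c-Myb, AML1-ETO and progenitors. Of the fixed set, Crebbp and Kit had no named probe among those tested, and the probes of Jup and Sox4 did not pass the detection filter.

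The steps were tested on simulated data for 12760 probes with 100 probes changed by 1 and 100 by 2 on the log2 scale. For AML1-ETO9a in wild-type cells 36 and 81 of the 100 were recovered, in Booreana cells 37 and 73. For Booreana against wild-type the numbers were 35 and 94 with the control vector and 44 and 84 with AML1-ETO9a. For the difference of responses they were 10 and 54, so a difference of that kind is missed often at this size. False calls made up 5.65%, 5.17%, 6.52%, 3.03% and 0% of the calls in the same order. Each simulated probe had the same spread in all 4 groups, and arrays were not paired. The numbers therefore do not show whether changes are found equally well in the real arrays of both genotypes.

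Replicate numbers were checked for pairing. Deviations from the group mean of same-numbered control and AML1-ETO9a arrays correlated at 0.167 to 0.708 in wild-type cells, where 3 of 4 arrays matched their own number best, and at 0.362 to 0.418 in Booreana cells, where 4 of 4 did. The numbers were therefore taken to pair the arrays within a genotype, on the evidence of the data alone. The main model was set before this check and leaves the pairing out, so its calls and adjusted p-values for AML1-ETO9a do not use it. The replicate block does so for AML1-ETO9a and for the difference of responses, and what changes with it is given beside the results. Across genotypes the numbers did not pair (-0.507 to 0.329 with the control vector, -0.251 to 0.168 with AML1-ETO9a). For Booreana against wild-type the block still joined equal numbers of all groups. Its values there do not rest on a pairing that the data show. No arrays held identical values, and the highest correlation between 2 arrays was 0.985. Alternatives covered background correction, normalization, the detection filter, the authors' values, array weights, the spread model, the arrays in the fit, 1 value per gene, the replicate block and leaving out each array. The files name no chips, so chip was not tested as a batch.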

Results

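Expression was measured on 16 arrays of mouse bone marrow progenitors that carry c-Kit, 48 hours after retroviral transduction. The 4 groups of 4 arrays crossed genotype (wild-type C57Bl/6 or Booreana) with virus (control vector or AML1-ETO9a). Booreana mice carry a mutation in Myb, which encodes c-Myb, a transcription factor needed by blood progenitors. AML1-ETO9a is a short splice form of the fusion protein of RUNX1 (AML1) and RUNX1T1 (ETO) made in acute myeloid leukemia with an exchange between chromosomes 8 and 21. The series title ties the work to the role of c-Myb's binding to p300, a coactivator, in leukemia driven by human oncogenes. The median intensity of an array lay between 189 and 250, and 39.5% to 46.7% of probes were detected per array. All log2 values below are normalized, with 4 arrays per group.

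The first principal component, with 34.8% of the variance, mostly set 1 array apart, Booreana control replicate 2, at 128. On the second, with 19.2%, the wild-type control arrays lay highest, between 26.7 and 41.6, and the Booreana AML1-ETO9a arrays between -54.7 and -24.3. The other groups lay between 2.62 and 20.5 (wild-type AML1-ETO9a) and between -36.7 and 7.77 (Booreana control), so those of Booreana cells overlapped. This array had the fewest detected probes (10158, against up to 12002) and a mean correlation with the other arrays of 0.845, where the others lay between 0.931 and 0.955. It stayed in every comparison, and counts without it are given where they differ by over 1.5 times.

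**Figure D1:**
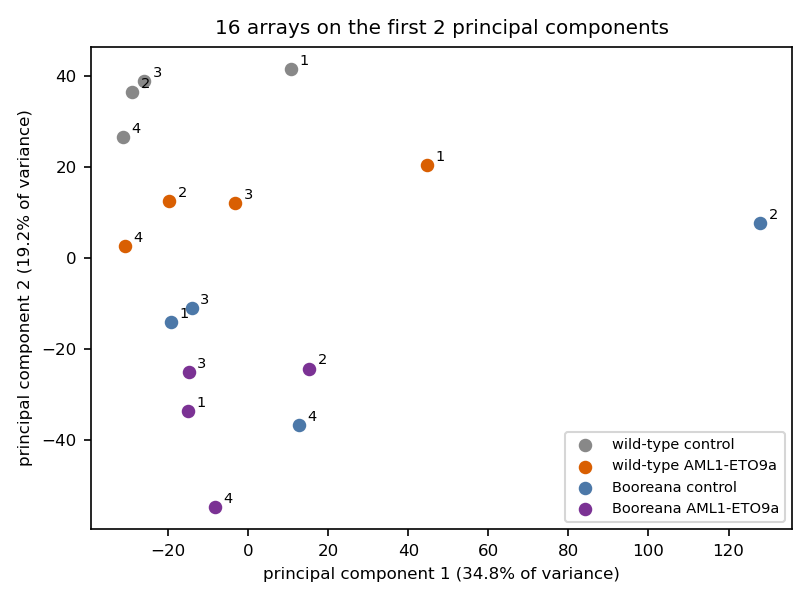
Position of the 16 arrays on principal components 1 and 2 of the normalized log2 signals, with replicate numbers beside the points and colours for the 4 groups. Booreana control replicate 2 lies at 128 on component 1, far from the other arrays, and component 2 holds 19.2% of the variance.

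Among the genes the study turns on, Myb itself did not pass the test in any comparison. The probe was dim: its group means were 5.32 ± 0.39 (SD, n = 4) in wild-type control, 5.55 ± 0.34 in wild-type AML1-ETO9a, 6.38 ± 0.87 in Booreana control and 5.96 ± 0.15 in Booreana AML1-ETO9a cells, and it was detected on 1, 1, 3 and 4 arrays. Booreana minus wild-type was 1.05 ± 0.34 with the control vector (adjusted p = 0.0855, and 0.00894 without Booreana control replicate 4), and another probe gave 0.00. The highest Booreana control value, 7.38, lay on replicate 2, the array set apart, and the others were 6.11, 6.68 and 5.33. An expression probe does not read the mutation. Ep300, the gene of p300, was also not past the threshold, with values from -0.45 to 0.45 in the 4 group comparisons; without Booreana control replicate 2 the lowest and highest of these became 0.08 and -0.08. Runx1, the mouse counterpart of the first fusion partner, rose by 1.33 ± 0.23 with AML1-ETO9a in wild-type cells (adjusted p = 0.00259) and was at 0.44 ± 0.23 in Booreana cells, not past the threshold. Runx1t1, the counterpart of the second, was detected on all 4 Booreana AML1-ETO9a arrays and on 0 arrays of the other 3 groups. It was at least 1.93-fold higher there than in Booreana control cells (adjusted p = 0.00051) and at least 2.03-fold higher than in wild-type AML1-ETO9a cells (adjusted p = 0.000273). Whether this mouse probe or that of Runx1 reads the viral fusion transcript is not known here, so neither checks the labels. For Runx1t1 the difference of the 2 responses was not past the threshold (adjusted p = 0.0829, and 0.0473 without Booreana AML1-ETO9a replicate 4).

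AML1-ETO9a in wild-type cells was set against the control vector to find its early effect on normal progenitors. Ch25h, which makes 25-hydroxycholesterol, rose by 5.22 ± 0.34 on the log2 scale (adjusted p = 9.08e-07) and Car4, a carbonic anhydrase, rose 29.9-fold (4.90 ± 0.33, adjusted p = 9.08e-07). Chemokines that attract monocytes and neutrophils rose as well: Ccl7 by 4.60 ± 0.72, Ccl12 by 4.18 ± 0.51, Ccl2 by 4.07 ± 0.52, and Cxcl2 at least 9.99-fold. Arg1, which splits arginine (4.30 ± 0.89), Ppbp, a platelet chemokine (4.32 ± 0.85), the surface proteins Sdc4 (3.74 ± 0.53), Flrt3 (3.69 ± 0.39) and Pdpn (3.57 ± 0.38), and Gstt1 (3.68 ± 0.47) completed the largest rises. The largest falls were in Prss34, a basophil protease (-3.11 ± 0.67), Septin5 (-2.98 ± 0.47), Gal (-2.77 ± 0.48), the adhesion molecule Vcam1 (-2.76 ± 0.28) and the transcription factor Ets1 (-2.75 ± 0.41). Next came Rasl11b (-2.68 ± 0.45), Akr1c18 (-2.66 ± 0.50), Igfbp7 (-2.63 ± 0.48), Nkg7 (-2.63 ± 0.38), Cebpa, the master regulator of granulocyte development (-2.53 ± 0.46, adjusted p = 0.00361), Ifitm6 (-2.53 ± 0.63) and Tspan2 (-2.51 ± 0.27). The call of Ifitm6 (adjusted p = 0.0309) ended without any of 3 single arrays (up to 0.0937). Without 1 array, Ppbp was at 5.09 (wild-type control replicate 4) and Ifitm6 at -1.73 (wild-type AML1-ETO9a replicate 4). Ch25h, Flrt3, Gstt1, Cebpa and, below, Id3 were detected on 1 of 4 arrays of their lower group, so the sizes of these changes rest on background.

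Neutrophil primary granule genes fell in wild-type cells with AML1-ETO9a: of 9 measured, 4 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -1.07 (fry adjusted p = 3.57e-07, and 0.00368 with an estimated correlation). Elane, neutrophil elastase, fell by 2.27 ± 0.25 and Prtn3, proteinase 3, by 1.44 ± 0.23, while Ctsc, the protease that activates them, rose by 0.94 ± 0.19. Gfi1, a repressor needed for neutrophil development, fell by 1.07 ± 0.23 (adjusted p = 0.0126, and 0.0508 without wild-type AML1-ETO9a replicate 3). Of 16 late granule genes 3 fell (5 adjusted over the list alone), among them Orm1, at least 3.29-fold lower, and Cebpe (-1.34 ± 0.22, other probe -1.42, not past the threshold). That list's call (adjusted p = 0.0468, and 0.326 with an estimated correlation) was lost without any of 12 of the 16 single arrays, with adjusted p up to 0.14. Of 16 genes that earlier work reports as lowered by AML1-ETO, 6 fell and 1 rose (7 and 2 adjusted over the list alone, adjusted p = 0.000338, and 0.0296 with an estimated correlation). Cd14, a monocyte receptor in that list, was the one that rose (1.60 ± 0.25). Elane and Cebpa, which fell, belong both to that list and to the primary granule list. Cebpe belongs both to that list and to the late granule list, so these lists are not separate evidence. Of 5 genes reported as raised, Cdkn1a, a cell cycle inhibitor, rose (0.85 ± 0.19, adjusted p = 0.016, other probes 1.20 and 0.73, not past the threshold), 2 rose adjusted over the list alone, and the list gave adjusted p = 0.0212 (0.268 with an estimated correlation). Its call ended without wild-type AML1-ETO9a replicate 1 or 3 or wild-type control replicate 2 or 4 (adjusted p up to 0.0745), and that of Cdkn1a without wild-type control replicate 3 (0.0718) or wild-type AML1-ETO9a replicate 4 (0.0501).

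Inflammatory and immediate early genes rose in the same wild-type comparison. Of 20 NF-kB targets and cytokines 5 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.92, adjusted p = 0.00273), including Icam1 (1.76 ± 0.26) and Socs3 (1.05 ± 0.18). Of 16 immediate early genes 2 rose, Ier3 (1.31 ± 0.17) and Dusp2 (1.70 ± 0.36), or 4 adjusted over the list alone, with a median of 0.68 (adjusted p = 0.00259). With an estimated correlation the NF-kB list had adjusted p = 0.129 and the immediate early list adjusted p = 0.0915. Of 13 monocyte and macrophage genes 3 rose (4 adjusted over the list alone): Adgre1, the F4/80 antigen (1.66 ± 0.17, another probe at 1.19, not past the threshold), Cd14, and Mrc1, the mannose receptor (3.17 ± 0.60). That list had adjusted p = 0.0468, and 0.446 with an estimated correlation, and its call was lost without any of 13 single arrays (adjusted p up to 0.116).

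Cholesterol synthesis genes fell in wild-type cells, 2 of 14 past the threshold and 4 adjusted over the list alone, with a median of -0.57 (adjusted p = 0.000478, and 0.0296 with an estimated correlation). Fdps, an enzyme of the farnesyl step, fell by 0.97 ± 0.19. S phase genes had a median of -0.28 (1 of 20 fell, 2 adjusted over the list alone, adjusted p = 0.0152, and 0.138 with an estimated correlation). For G2 and mitosis the median was -0.29, with 0 of 15 past the threshold by either adjustment (adjusted p = 0.0399, and 0.167 with an estimated correlation). That call was lost without any of 8 single arrays, up to 0.133. Eosinophil genes fell, 3 of 5 by both adjustments (median -1.38, adjusted p = 0.0212, and 0.167 with an estimated correlation), with Prg3, an eosinophil granule protein, at -2.35 ± 0.50. Without wild-type control replicate 1, 2 or 4 the adjusted p was up to 0.0632. The T and NK cell list held only Nkg7 and 1 other measured gene, of which Nkg7 fell (1 adjusted over the list alone, adjusted p = 0.0133, 0.167 with an estimated correlation, and 0.0502 without wild-type control replicate 2).

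Progenitor genes moved individually. Cd34, a marker of stem and progenitor cells, rose by 2.60 ± 0.29 (adjusted p = 5.34e-05), as did Id3, an inhibitor of basic helix-loop-helix factors (2.57 ± 0.38). The early progenitor list was not past the threshold (1 of 13 rose by both adjustments, adjusted p = 0.243). The list of c-Myb-activated genes, to which Cd34, Elane and Gfi1 also belong, had 2 rises and 3 falls among 13 (3 and 4 adjusted over the list alone, median -0.54, adjusted p = 0.0212, and 0.167 with an estimated correlation). Without wild-type AML1-ETO9a replicate 2 or 3 or wild-type control replicate 1 or 4 its adjusted p was up to 0.0632. Pf4, a platelet chemokine, rose by 2.26 ± 0.42, and Mcpt8, a basophil protease, fell by 2.25 ± 0.36, while the megakaryocyte (adjusted p = 0.404), mast cell and basophil (0.697) and erythroid (0.334) lists were not past the threshold. Of 29 hematopoietic transcription factors 4 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.422). Spi1, Gata1, Gata2, Myc, Bcl2, Id1, Hoxa9 and Meis1 did not pass, with values from -0.69 to 0.74.

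In all, 551 of 12760 probes were called in wild-type cells, 315 higher and 236 lower with AML1-ETO9a. The count was 959 with the replicate block and 355 without wild-type control replicate 3, and 770 without Booreana control replicate 2. Without normalization between arrays it was 336, with 229 higher and 107 lower (68.2% higher against 57.2%), and 11 of the 13 list calls ended; those of primary granules and NF-kB stayed. With the block the B cell (adjusted p = 0.0199), glycolysis (0.0482) and cytokine receptor (0.0264) lists passed as well. Glycolysis also passed with the authors' values (0.0457) and without Booreana control replicate 2 (0.0163). The stromal list tested as lower without background correction (0.0251) and with the authors' values (0.0181).

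**Figure D2:**
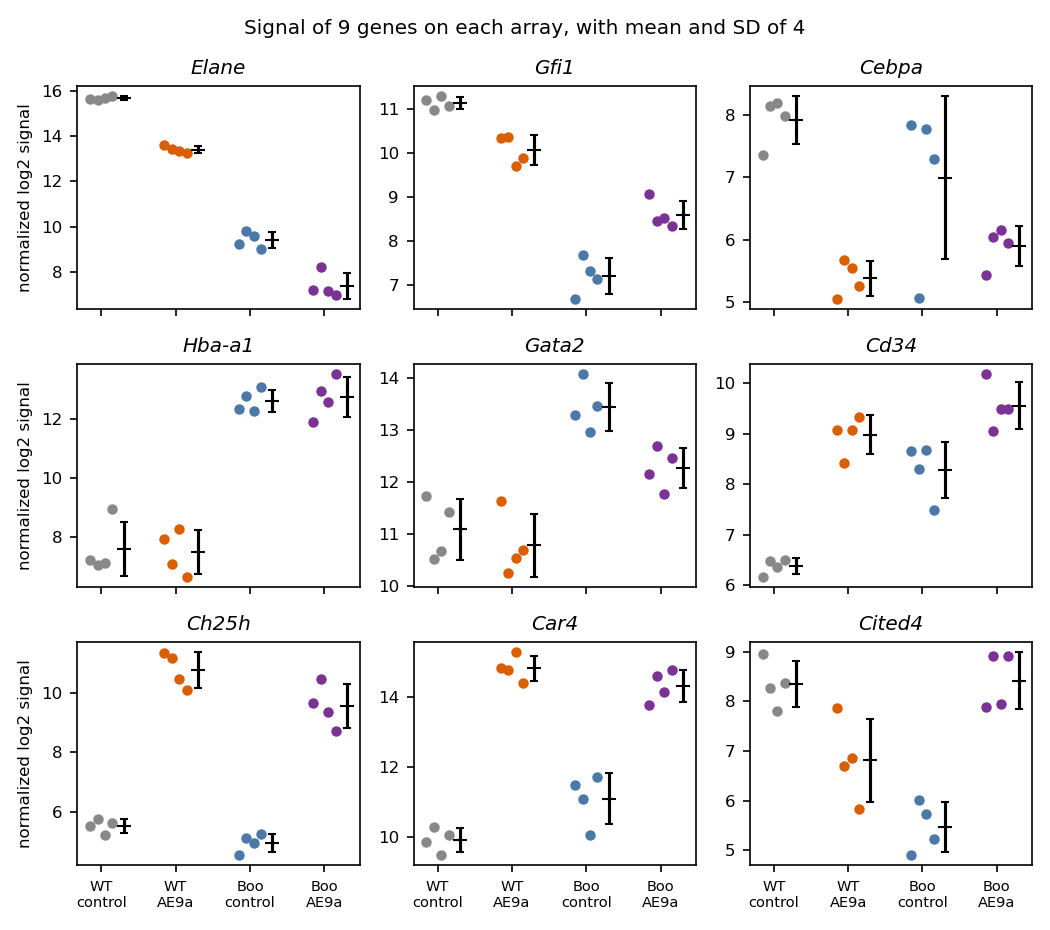
Normalized log2 signal of 9 genes on each array (points), with the mean and SD of the 4 arrays of each group (bars), for wild-type (WT) and Booreana (Boo) cells with control vector or AML1-ETO9a (AE9a). Elane lies at a mean of 15.67 in wild-type control cells and 9.40 in Booreana control cells, and Cited4 moves in opposite directions with AML1-ETO9a in the 2 genotypes.

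In Booreana cells AML1-ETO9a was set against the control vector in the same way, to find which effects occur with mutant c-Myb. Ch25h rose at least 13.9-fold (adjusted p = 7.81e-06) and Car4 by 3.23 ± 0.33, and the chemokine genes Ccl7 (3.65 ± 0.72), Ccl2 (3.08 ± 0.52) and Cxcl2 (at least 3.45-fold) rose too. Other large rises were Slc45a3 (at least 13.4-fold), Tph1, which starts serotonin synthesis in mast cells (at least 12.9-fold), Gask1b (3.93 ± 0.39), Rab15 (3.89 ± 0.38), the growth factor Vegfc (3.84 ± 0.40), Amigo2 (3.56 ± 0.49), Cd59a (3.54 ± 0.41), Spink2 (3.40 ± 0.48) and Tpsab1, a mast cell tryptase (at least 6.05-fold). The largest falls were in Prss34 (-3.18 ± 0.67), Igfbp7 (-3.02 ± 0.48), B4galnt4 (at least 5.15-fold lower), Mpo, myeloperoxidase (-2.86 ± 0.55), Nkg7 (-2.58 ± 0.38), Mcpt8 (-2.40 ± 0.36), Rnase12 (-2.30 ± 0.27), Bace1 (-2.07 ± 0.31) and Elane (-2.02 ± 0.25). Nrp1 (-2.00 ± 0.24), Ifitm1 (-2.00 ± 0.24) and Hsd17b1 (-1.95 ± 0.34) followed. The other probes of Mpo (-0.76 and -1.74) and of Ifitm1 (-2.08 and -1.15) were not past the threshold. Calls ended without single arrays for Ccl7 (Booreana AML1-ETO9a replicate 4, 0.0571, and control replicate 3, 0.0552), Tph1 (AML1-ETO9a replicates 2 and 4 and control replicate 3, up to 0.0638) and Prss34 (AML1-ETO9a replicates 1, 2 and 3 and control replicate 4, up to 0.0797). Without 1 array, Ccl7 was at 2.98 (Booreana control replicate 1) or 4.36 (replicate 4), Prss34 at -2.59 (replicate 4), and Mpo at -2.21 (Booreana AML1-ETO9a replicate 4). The fitted change of Tph1, which rests on background, was 4.44 with all arrays. It was 5.18 without Booreana AML1-ETO9a replicate 3 and 3.55 without replicate 4.

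Of the fixed genes, Gfi1 rose in Booreana cells with AML1-ETO9a (1.39 ± 0.23, adjusted p = 0.00406). Cebpa was at -1.10 ± 0.46, Gata2 at -1.17 ± 0.34 and Bcl2 at -0.77 ± 0.37, not past the threshold. With the replicate block Gata2 fell (adjusted p = 0.00444), and 1 other probe of Bcl2 fell by 1.56 (adjusted p = 0.0107) without the block. Without Booreana control replicate 2, Cebpa (-1.74, adjusted p = 0.00122) and Bcl2 (-1.20, adjusted p = 0.0434) passed. Slamf1, a marker of stem cells, rose at least 2.81-fold, Id3 by 2.27 ± 0.38 (detected on 1 of 4 control arrays) and Cd34 by 1.27 ± 0.29. The call of Cd34 (adjusted p = 0.0349) ended without any of 8 single arrays, with adjusted p up to 0.113.

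Primary granule genes fell in Booreana cells with AML1-ETO9a too: 2 of 9 fell and 1 rose (3 and 1 adjusted over the list alone, median -0.50, adjusted p = 0.000693, and 0.171 with an estimated correlation). The AML1-ETO-lowered list had 2 falls of 16 (3 adjusted over the list alone, median -0.25, adjusted p = 0.0103, and 0.193 with an estimated correlation). Both lists contain Mpo and Elane, which were the 2 falls in each, so these are not separate results. Eosinophil genes fell, 1 of 5 past the threshold and 4 adjusted over the list alone, with Alox15, then detected on 1 of 4 arrays, at -1.63 ± 0.30 (adjusted p = 0.0111, and 0.171 with an estimated correlation). Cholesterol synthesis genes had a median of -0.36, with 0 of 14 past the threshold and 2 adjusted over the list alone (adjusted p = 0.00975, and 0.171 with an estimated correlation). Of the 2 measured T and NK cell genes Nkg7 fell, or both adjusted over the list alone (adjusted p = 0.000722, and 0.146 with an estimated correlation). The stromal list rested on Sparc, a matrix protein at least 2.47-fold higher, among 4 genes (1 adjusted over the list alone, adjusted p = 0.03, and 0.171 with an estimated correlation). It lost its call without any of 6 single Booreana arrays (up to 0.0836), and Sparc without AML1-ETO9a replicate 2 (0.0547) or control replicate 3 (0.054). Not past the threshold were the immediate early (adjusted p = 0.0531), NF-kB (0.178), late granule (0.654) and monocyte (0.274) lists. Without Booreana control replicate 4 the immediate early, DNA repair, stress response and cytokine receptor lists passed (0.0387 each), as did the NF-kB, monocyte, megakaryocyte, c-Myb-activated and glycolysis lists (0.0473 each). Cytokine receptors also passed without Booreana AML1-ETO9a replicate 1 (0.039), and immediate early genes without Booreana AML1-ETO9a replicate 3 (0.029), Booreana control replicate 2 (0.045), wild-type AML1-ETO9a replicate 1 (0.0499) or 4 (0.0478) or wild-type control replicate 4 (0.0441). With the replicate block 10 more lists passed, among them immediate early (adjusted p = 0.00314), monocyte (0.00324), Myc targets (0.00507, median -0.26), NF-kB (0.00954), cytokine receptors (0.00954), c-Myb-activated (0.00986, median -0.18), stress response (0.0253), megakaryocyte (0.0262), DNA repair (0.0436, median -0.21) and p53 targets (0.0482). With camera's preset correlation the immediate early (0.00167), NF-kB (0.00365), cytokine receptor (0.00603), stress response (0.00803), monocyte (0.0181) and megakaryocyte (0.0359) lists passed.

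The Booreana comparison called 210 probes, 134 higher and 76 lower. The count was 453 with the replicate block, 113 among probes detected on all arrays, 63 when fitted on the 8 Booreana arrays alone, and 139 without Booreana control replicate 3. The share of calls that were higher (63.8%) became 86.1% without normalization between arrays (149 against 24) and 52.0% with median scaling (106 against 98), where the median of all probes moved from -0.03 to -0.15.

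Most of the wild-type response had the same sign in Booreana cells. Of probes called in wild-type cells, 288 of 315 rises (91.4%) and 208 of 236 falls (88.1%) kept their sign. Called in both genotypes were 77 rises (3.31 expected of independent lists) and 42 falls (1.41). Across all probes the 2 responses correlated at 0.338 (Spearman 0.173), where probes are not independent replicates. In size, the Booreana response was 0.555 of the wild-type one over 36 splits (range 0.364 to 0.757), with mean changes of 1.02 and 1.81 on the log2 scale. The probes were chosen by their wild-type change alone, which by itself favours a larger change in wild-type cells. The reverse choice, on Booreana arrays, was not run, so this value does not show a smaller Booreana response. Of the 430 probes called in wild-type cells alone, 7 differed between genotypes by the test of the difference, as did 2 of the 89 called in Booreana cells alone.

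**Figure D3:**
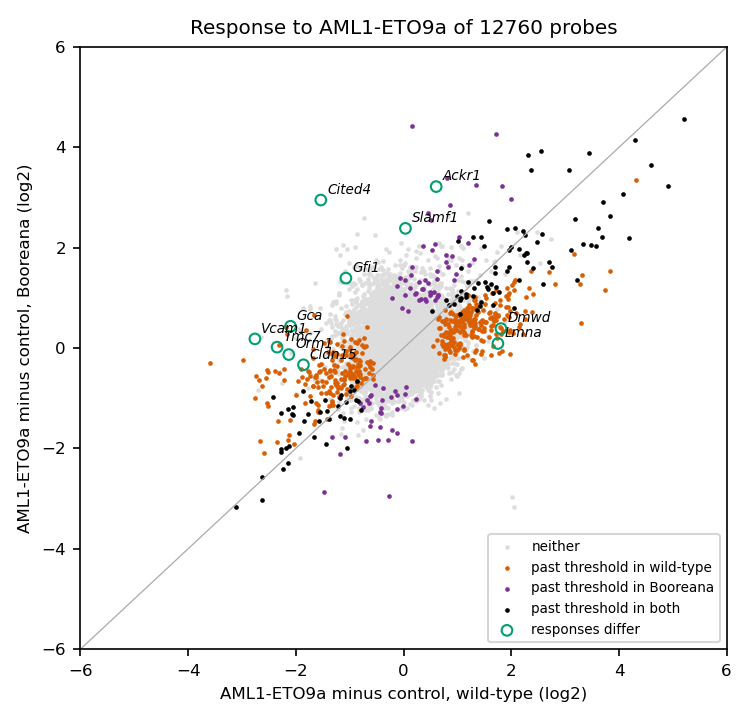
Change with AML1-ETO9a in wild-type cells (horizontal axis, log2) and in Booreana cells (vertical axis, log2) for the 12760 probes, coloured by the genotype in which a probe passed the threshold, with the line of equal change. Rings mark the 11 probes whose responses differ, of which Cited4 lies highest above the line.

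The test of the difference itself called 11 probes. Cited4, a coregulator that binds p300, fell by 1.54 ± 0.40 with AML1-ETO9a in wild-type cells (adjusted p = 0.0392, with arrays that overlapped) and rose by 2.95 ± 0.40 in Booreana cells, with adjusted p = 0.00522 for the difference. It was detected on 1 of 4 Booreana control arrays, so the size of that rise rests on background. Gfi1 likewise fell by 1.07 ± 0.23 in wild-type and rose by 1.39 ± 0.23 in Booreana cells (difference 2.46 ± 0.33, adjusted p = 0.00522). Ackr1, a chemokine-binding receptor, rose in Booreana cells (adjusted p = 0.0241 for the difference) and was detected on 0 and 2 of 4 wild-type arrays with control vector and AML1-ETO9a, so its size was not measured. Slamf1 (adjusted p = 0.0166) was detected in Booreana AML1-ETO9a cells alone, so the size of its difference was not measured. Vcam1 (adjusted p = 0.00522), Orm1 (0.00522) and Tmc7 (0.0136) fell in wild-type cells. In Booreana control cells they were detected on 1, 0 and 0 of 4 arrays, so neither a fall there nor the size of the difference could be measured. Lmna, nuclear lamin A, rose in wild-type cells and was at 0.09 in Booreana cells (difference -1.66 ± 0.27, adjusted p = 0.0241), and its 4 other probes (-1.11 to -1.52) were not past the threshold. Outside the rule for named genes, and chosen after their values were seen, the remaining 3 probes belonged to Gca (2.53 ± 0.43, detected on 2 of 4 Booreana control arrays), Cldn15 and Dmwd (-1.42 ± 0.22). This Cldn15 probe (adjusted p = 0.0339) was detected in wild-type control cells alone, so a fall in Booreana cells could not be measured. Gca, Cldn15 and Dmwd each had a brighter tested probe, which was not past the threshold for the difference.

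Of the lists, primary granule genes alone passed in the difference: 1 of 9, Gfi1, was higher by both adjustments (median 0.25, adjusted p = 0.0303), with adjusted p = 0.38 with an estimated correlation and 0.17 with the replicate block. That call ended without any of 5 single arrays, Booreana AML1-ETO9a replicate 2, Booreana control replicate 1, wild-type AML1-ETO9a replicate 2 and wild-type control replicates 2 and 4 (up to 0.0767). The stromal (0.0389), Myc target (0.0349) and NF-kB (0.0389) lists passed with the block. The stromal list also passed without background correction (0.00995), with the authors' values (0.00936), without normalization between arrays (0.00407) and without Booreana AML1-ETO9a replicate 3 (0.0235), Booreana control replicate 4 (0.0488) or wild-type AML1-ETO9a replicate 4 (0.0296). The c-Myb-activated list passed with the authors' values (0.0179), and the late granule (1.59e-07) and NF-kB (0.0243) lists with camera's preset correlation. Late granule genes had the highest median difference, 1.01, with 1 of 16 past the threshold, Orm1, by both adjustments (adjusted p = 0.342). The count of 11 was 37 with the block, 3 among probes detected on all arrays (1 higher, 2 lower), 6 without normalization between arrays (6 higher, 0 lower), and 6 without wild-type AML1-ETO9a replicate 2. The call of Ackr1 ended without any of 8 single arrays and that of Lmna without any of 6 (both up to 0.0851), and that of Slamf1 without wild-type AML1-ETO9a replicate 2 (0.0544). At an unadjusted p under 0.05 there were 850 probes, where a share of 0.05 of the 12760 tested passes without any difference. Median scaling moved the median of all probes from -0.05 to -0.18.

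Booreana control cells were set against wild-type control cells to find what differs between the genotypes without the oncogene. The arrays read sorted cells in bulk, so changes within cells cannot be told apart from a different mix of cells. Several granule genes were far lower in Booreana cells. Elane was 77.1-fold lower (-6.27 ± 0.25, adjusted p = 7.55e-10) and Mpo was at -5.27 ± 0.55 (other probes -6.44 and -6.41). Prtn3 (-3.66 ± 0.23), Ctsg, cathepsin G (-3.36 ± 0.24), and Gfi1 (-3.94 ± 0.23) were also lower. In the opposite direction, globin genes were higher, Hba-a1 by 5.04 ± 0.46 and Hbb-bt by 4.35 ± 0.45, as were the transcription factors Gata2 (2.36 ± 0.34), Gata1 (2.04 ± 0.39), Meis1 (2.54 ± 0.26) and Runx1 (1.08 ± 0.23).

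Further large rises in Booreana control cells were Bex4 (5.39 ± 0.37), Igfbp5 (4.59 ± 0.51), Retnla (at least 15-fold), Ccl24, an eosinophil chemokine (4.17 ± 0.88), Avil (4.01 ± 0.48), the ribonuclease Rnase2a (at least 7.66-fold), Aldh3a1 (3.39 ± 0.33), Havcr2 (at least 8.47-fold), Mllt3 (3.20 ± 0.47) and Rgs1 (3.20 ± 0.37, 1 other probe at 1.71, not past the threshold). Further falls were Vcam1 (-4.92 ± 0.28), Fcnb (-4.53 ± 0.50), Mmp2 (at least 14.0-fold lower), Gstm2 (-3.85 ± 0.30), Tmc7 (at least 6.42-fold lower) and F13a1 (-3.62 ± 0.40). Vcam1, Gstm2 and F13a1 were detected on 1 of 4 Booreana control arrays, and Gata1 on 1 of 4 wild-type ones, so these sizes rest on background. Without Booreana control replicate 1, the folds of Ccl24, Casp9 and Rnase2a were over 1.5 times larger. The fitted change of Rnase2a, which rests on background, was 3.48 with all arrays, 4.36 without that array and 2.80 without Booreana control replicate 4. Casp9, the initiator caspase of the mitochondrial pathway, was at -3.95 ± 0.93 (adjusted p = 0.016, and 0.0552 without Booreana control replicate 4), while its other probe was at 1.00, not past the threshold (adjusted p = 0.14). Cdkn1a was higher (0.85 ± 0.19, adjusted p = 0.0114, and 0.0506 without wild-type control replicate 3), but its other probes, at 1.17 and 0.03, were not past the threshold. Cebpa (-0.93 ± 0.46), Spi1, Myc, Bcl2, Id1 and Hoxa9 (-0.62 to 0.27) were not past the threshold, and without Booreana control replicate 2 Cebpa was at -0.28 and Myc at 0.34 instead of -0.62.

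Markers of several lineages moved together with genotype. Of 9 primary granule genes 6 were lower by both adjustments (median -3.36, adjusted p = 2.42e-12, and 7.64e-05 with an estimated correlation). Of 16 late granule genes 3 were lower (5 adjusted over the list alone, adjusted p = 0.0136, 0.254 with an estimated correlation, and 0.0539 without Booreana control replicate 4), with Orm1 at least 3.13-fold lower. Erythroid genes were higher, 5 of 10 (6 higher and 1 lower adjusted over the list alone, median 1.12, adjusted p = 0.000234, and 0.145 with an estimated correlation), such as Aqp1, the water channel (1.86 ± 0.35). Megakaryocyte genes were higher, 4 of 15 (6 adjusted over the list alone, median 0.77, adjusted p = 0.00441, and 0.215 with an estimated correlation), with Itga2b (CD41) at 2.83 ± 0.45 (another probe at 1.70, not past the threshold) and Gp5 at 1.73 ± 0.30. Mast cell and basophil genes were higher, 8 of 15 (8 higher and 1 lower adjusted over the list alone, median 1.14, adjusted p = 0.0062, and 0.295 with an estimated correlation), including the cytokine Il4 (3.18 ± 0.41), Slc18a2 (2.21 ± 0.34) and Ms4a2, a chain of the IgE receptor (1.84 ± 0.27).

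MHC class II and dendritic cell genes were higher, 6 of 10 (8 adjusted over the list alone, median 1.52, adjusted p = 0.00101, and 0.166 with an estimated correlation), with H2-Eb1 at 2.07 ± 0.32 and Cd74 at 1.86 ± 0.28. Of 13 early progenitor genes 5 were higher by both adjustments, among them Cd34 (1.91 ± 0.29), Meis1 and Mllt3 (median 0.28, adjusted p = 0.00125, and 0.254 with an estimated correlation). Of 29 hematopoietic transcription factors 9 were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.0017, and 0.215 with an estimated correlation), including Zfpm1, a partner of Gata1 (2.22 ± 0.21), and Gfi1b (2.00 ± 0.33). The c-Myb-activated list had 2 higher and 3 lower of 13 by both adjustments (median -0.38, adjusted p = 1.08e-06, and 0.145 with an estimated correlation), and the lower ones were the granulocyte genes Elane, Mpo and Gfi1. The AML1-ETO-lowered list had 1 higher, Lat2 (1.71 ± 0.27), and 4 lower of 16 (1 and 5 adjusted over the list alone, median -0.53, adjusted p = 2.46e-06, and 0.053 with an estimated correlation). Elane, Mpo and Ctsg, among the lower ones, also belong to the primary granule list. The stromal list of 4 tested as lower on the fall of Vcam1 (1 lower, or 1 higher and 1 lower adjusted over the list alone, mean -1.01, adjusted p = 0.000234, and 0.447 with an estimated correlation) although its median was 0.13.

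Weaker calls in Booreana control cells were the AML1-ETO-raised list (2 higher and 1 lower of 5 by both adjustments, adjusted p = 0.0365, and 0.447 with an estimated correlation), p53 targets (2 higher and 1 lower of 19, 3 and 1 adjusted over the list alone, adjusted p = 0.0394, and 0.447 with an estimated correlation) and immediate early genes (1 of 16 by both adjustments, adjusted p = 0.0365, and 0.419 with an estimated correlation). Each was lost without any of 5 single arrays, with adjusted p up to 0.284, 0.18 and 0.12. Fas, a death receptor in the p53 list, was lower (-1.07 ± 0.20, other probe -1.01, not past the threshold). The NF-kB list (3 of 20 higher, 3 higher and 2 lower adjusted over the list alone, adjusted p = 0.175) passed with the replicate block (0.0296), as did glycolysis (0.0173). That block joins equal numbers across genotypes, which were not found to pair. Glycolysis also passed without Booreana control replicate 2 (0.00375), and the T and NK cell list without Booreana control replicate 1 (0.0296). Il6, an inflammatory cytokine, was higher by 2.56 ± 0.31. In all, 810 probes differed, 481 higher and 329 lower in Booreana cells. The count was 516 when fitted on the 8 control arrays alone and 535 among probes detected on all arrays.

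With AML1-ETO9a in both genotypes, Booreana cells differed from wild-type cells along the same lines. Mpo was at -6.66 ± 0.55 (-6.00 without Booreana AML1-ETO9a replicate 4, other probes -4.57 and -6.02), Elane 64.7-fold lower (-6.02 ± 0.25), and Ctsg (-3.43 ± 0.24) and Prtn3 (-2.72 ± 0.23) were lower. Retnla (5.91 ± 0.49), Bex4 (5.55 ± 0.37), Igfbp5 (5.47 ± 0.51), Hba-a1 (5.26 ± 0.46) and Fcer1a, the alpha chain of the IgE receptor (4.79 ± 0.60), were higher. Saa3, an acute phase protein, was lower (-4.66 ± 0.31).

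Other large differences with AML1-ETO9a were higher Rnase2a (at least 20.3-fold), Ackr1 (3.91 ± 0.30), Aldh3a1 (3.63 ± 0.33), Avil (3.43 ± 0.48), Spink2 (3.25 ± 0.48), Akr1c18 (3.22 ± 0.50) and Slc14a1 (3.15 ± 0.30). Lower were F13a1 (-3.46 ± 0.40), Myl10 (-3.38 ± 0.36), Mmp2 (-3.13 ± 0.24), Muc13 (-2.90 ± 0.31), Gpx3 (-2.71 ± 0.45) and the chemokine gene Ccl12 (-2.69 ± 0.51). Casp9 was at -4.17 ± 0.93 (adjusted p = 0.0181) and at 1.24 by its other probe (adjusted p = 0.0828), and the first call ended without Booreana AML1-ETO9a replicates 2, 3 or 4 or wild-type AML1-ETO9a replicates 2 or 4 (up to 0.0665), while without Booreana AML1-ETO9a replicate 1 it was at -5.19. Avil, F13a1, Mmp2 and this Casp9 probe were detected on 1 of 4 arrays of their lower group, so these sizes rest on background. Meis1 (2.41 ± 0.26), Gata1 (2.01 ± 0.39) and Gata2 (1.49 ± 0.34) were higher and Gfi1 lower (-1.47 ± 0.23); the call of Gata2 ended without any of 6 single arrays (up to 0.0835). Runx1 (0.20), Cebpa (0.51), Cdkn1a (0.42), Myb, Ep300, Spi1, Myc, Bcl2, Id1 and Hoxa9 (-0.40 to 0.43) did not pass.

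Primary granule genes were lower, 6 of 9 by both adjustments (median -2.26, adjusted p = 3.78e-11, and 0.00011 with an estimated correlation), whereas the late granule list was not past the threshold (0 of 16, adjusted p = 0.95). Erythroid genes were higher, 4 of 10 (9 higher and 1 lower adjusted over the list alone, median 1.28, adjusted p = 5.88e-05, and 0.0171 with an estimated correlation), with Aqp1 at 2.49 ± 0.35. Megakaryocyte genes were higher, 3 of 15 (6 adjusted over the list alone, adjusted p = 0.00149, and 0.0374 with an estimated correlation), with Gp5 at 2.38 ± 0.30 and Itga2b at 2.42 ± 0.45 (another probe at 2.46, not past the threshold). Mast cell and basophil genes were higher, 7 of 15 (8 higher and 1 lower adjusted over the list alone, median 1.19, adjusted p = 0.00476, and 0.0956 with an estimated correlation), such as Ms4a2 (2.20 ± 0.27). MHC class II genes were higher, 4 of 10 (7 adjusted over the list alone, median 1.01, adjusted p = 0.00925, and 0.104 with an estimated correlation), with H2-Eb1 at 1.58 ± 0.32. Of 13 early progenitor genes 5 were higher (6 higher and 1 lower adjusted over the list alone, median 0.89, adjusted p = 0.000901, and 0.057 with an estimated correlation), including Slamf1, at least 2.96-fold.

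The transcription factor list tested as higher with AML1-ETO9a, with 5 of 29 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.00139, and 0.0374 with an estimated correlation), with Zfpm1 at 1.68 ± 0.21. The c-Myb-activated list (1 higher and 4 lower of 13 by both adjustments, adjusted p = 9.43e-06, and 0.104 with an estimated correlation) and the AML1-ETO-lowered list (1 and 4 of 16 by both adjustments, adjusted p = 5.01e-05, and 0.282 with an estimated correlation) tested as lower. Their means were -0.89 each but their medians 0.04 and 0.09, and Mpo and Elane lay in both and in the primary granule list. Il6 was higher (2.82 ± 0.31) and Fas lower (-1.45 ± 0.20, other probe -0.90, not past the threshold), while the NF-kB (2 higher and 2 lower of 20, 2 and 4 adjusted over the list alone) and p53 lists were not past the threshold (0.702 and 0.124). In all, 477 probes differed, 296 higher and 181 lower (62.1% higher, and 77.3% without normalization between arrays, 296 against 87). The count was 252 among probes detected on all arrays. Of the 481 and 329 probes higher and lower with the control vector, 207 and 108 were called the same way with AML1-ETO9a (11.2 and 4.67 expected of independent lists), and 93.8% and 91.5% had the same sign. Equal replicate numbers were taken to pair the arrays of the 2 vectors within a genotype. The 2 lists are then not independent, and differences between animals could add to the shared calls.

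Lists not past the threshold in any comparison with fry, all arrays and no replicate block, in the processing described above, were apoptosis regulators (lowest adjusted p = 0.404), B cells (0.182), cytokine receptors (0.114), DNA repair (0.158), glycolysis (0.151), the interferon response (0.475), Myc targets (0.457) and the unfolded protein and amino acid stress response (0.1). The interferon response passed with AML1-ETO9a, Booreana against wild-type, with camera's preset correlation (0.0133), and the others but apoptosis regulators passed under the settings given with each comparison.

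**Figure D4:**
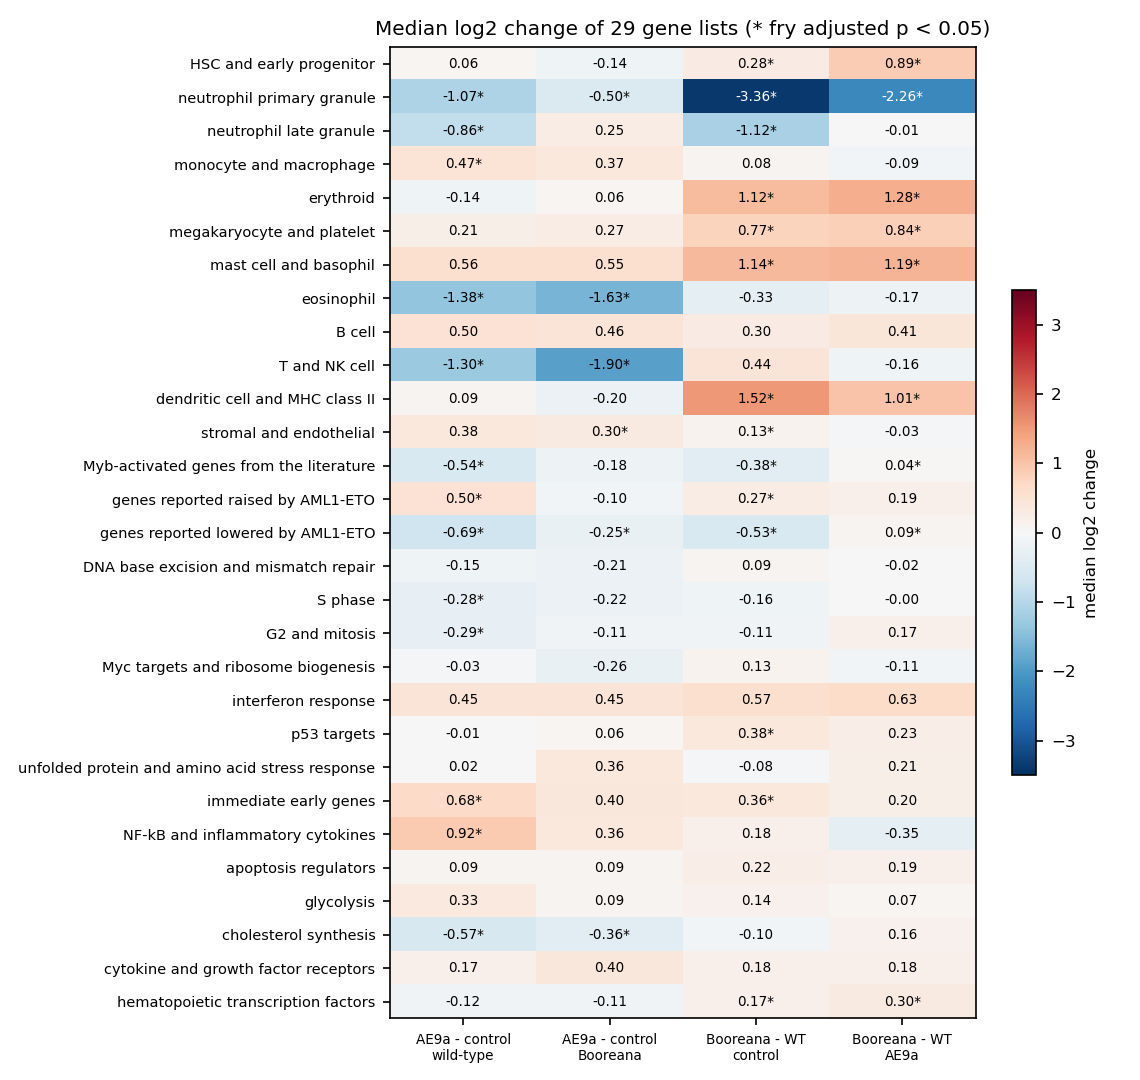
Median log2 change of the measured genes of the 29 lists (rows) in 4 comparisons (columns), with stars for a fry adjusted p under 0.05. Primary granule genes are lowest in Booreana minus wild-type control cells (-3.36); where the median lies above 0 and the test pointed down (stromal with the control vector, c-Myb-activated and AML1-ETO-lowered with AML1-ETO9a), the star stands for a fall.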

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

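The tests of Booreana control replicate 2 (its probes, its cell types and the spread it adds), the held-out and separate-control values of the Booreana response and the draws that keep the pairs were chosen after the result was seen. For cell types, the requirement that the spread of the list also lie under 1 log2 unit was added after its value was seen.

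Booreana control replicate 2 lay far from its group, with a mean correlation with the other arrays of 0.845 (0.935 to 0.950 for the other 3), and 225 of its probes lay at least 4 log2 units below those 3, where the highest number on another array was 12. Its deviations from them were little shared by 2 probes of a gene, with a correlation of 0.172 across 2295 genes against 0.797 for the genotype difference without this array and 0.268 to 0.499 for 7 other single arrays, which is consistent with noise of hybridisation or amplification at single probes. Of 108 genes with a probe that dropped by at least 4, the other probe lay within 1 log2 unit of its group in 70 and dropped too in 6, and abundant transcripts such as Lyz2 (5.86 against 13.3), Lcp1 (6.43 against 12.9) and Eef2 (5.15 against 11.3) were among the drops. Cells of another lineage cannot be told apart from this, because the highest median deviation of 12 lineage lists, 0.967 in 10 erythroid genes, had an upper quartile of 1.39, although the sort for c-Kit would remove mature red cells and the globin gene Hba-a1 (12.78) lay between the other Booreana controls (12.28 to 13.06). The design gives no biological explanation for a single array, and none was tested.

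The AML1-ETO9a response of wild-type cells went with the Booreana difference in control cells: 76 probes were higher in both (11.9 expected of independent lists), 80 were lower in both (6.08 expected) and 22 went opposite ways, with Elane, Vcam1, Septin5 and Bace1 lower in both and Cd34 and Pf4 higher in both. Both comparisons subtract the same wild-type controls, which alone gave a correlation of 0.498 in 20 simulations without effects (0.424 observed) but a covariance of 0.0683 (0.140 observed). The simulations gave 0 shared calls, but without effects hardly any probe can be called. They cannot say how many calls shared controls add where real changes exist. With different controls for each side the covariance was 0.103 (SD 0.00852 over 6 splits), and 0.0661 without Booreana control replicate 2, which argues against shared controls as the whole cause. With those separate controls the correlation was 0.282, with 24.2 probes higher and 27.8 lower in both (2.42 and 1.08 expected). Whether the oncogene and the c-Myb mutation act on these genes by the same route stays open, as untested.

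AML1-ETO9a changed fewer probes in Booreana than in wild-type cells, 210 against 551 at the adjusted threshold. At an unadjusted p under 0.05 the numbers were closer, 1569 against 1709. Both include the share of 0.05 of the 12760 tested probes that passes without any change. The gap stayed without Booreana control replicate 2, at 227 against 770 probes. It was 205 to 230 against 503 to 642 when 1 wild-type control was left out too. A covariate gave 898 and 989 with that array and 360 and 1242 without it. The 4 groups share 1 estimate of the spread, so spread from this array widens both comparisons. These counts therefore cannot decide whether added spread made the gap. Falls may be smaller because many of these genes already started lower: start and Booreana change, from different control arrays, correlated at -0.267 (-0.334 to -0.184 over 6 splits, -0.304 without that replicate), and of falls chosen with 2 wild-type controls 80.1% started lower against the other 2, where 49.8% of all probes did. On wild-type arrays not used to choose the probes the mean fall was -1.50, and -0.50 in Booreana cells. For rises that correlation was -0.0201 (-0.112 to 0.0899) and the means were 2.15 and 1.51, although 73.7% of rises chosen in the same way already started higher, so another reason, such as a weaker action of the oncogene with mutant c-Myb, stays open as untested. For falls and rises alike the probes were chosen by their wild-type change alone, which by itself favours larger means in wild-type cells.

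For the counts between genotypes, 1 of the 35 splits of the 8 arrays, the real one, gave as many probes in each. The counts were 810 and, for the highest other split, 2 with the control vector, and 477 and 1 with AML1-ETO9a. This argues against chance, at the smallest share that 35 splits can give. The other splits mix the genotypes, which puts a real difference into the spread and lowers their counts. The number of wild-type mice is not known, so chance between animals is not excluded. For AML1-ETO9a in wild-type cells the real split was also 1 of 35 (551, highest other 0), as in Booreana cells (210, highest other 29). Only 8 of these 35 part all 4 pairs of equal numbers, too few for a share under 0.05, and the highest other among them was 0 in both genotypes.

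A difference between the genotypes' responses passed its own test for Cited4 (4.49), Vcam1 (2.94), Ackr1 (2.61), Gca (2.53), Gfi1 (2.46), Tmc7 (2.37), Slamf1 (2.35), Orm1 (2.00), Lmna (-1.66), Cldn15 (1.52) and Dmwd (-1.42). The sizes of most of these rest on background: Slamf1, Orm1, Tmc7 and Cldn15 were detected on 0 arrays of at least 2 groups, Ackr1 and Vcam1 on 0 arrays of 1 group, and Cited4, Vcam1 and Gca on 1, 1 and 2 of 4 Booreana control arrays. For Gca, Cldn15 and Dmwd the brightest tested probe of the gene was not past the threshold, and the value given is from another probe. Of 100 free draws of the virus labels within genotype, 3, the real one included, called as many as 11 probes. The highest other, 338, kept the wild-type labels and gave the AML1-ETO9a label to 3 of 4 Booreana controls, so it nearly added the 2 responses (854 with all Booreana labels reversed), and such draws cannot show what chance gives for a difference. Of 100 draws that swap labels within pairs 11 called as many, the reversed labels among them. With the response shared by both genotypes removed first, the real labels alone did so, 1 of 100, and the highest other draw called 0. The other draws put a real difference of responses into the spread, which lowers their counts. This share alone therefore does not exclude chance.

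Wild-type control replicate 1 lay at 10.7 on principal component 1, apart from the other 3 arrays of its group (-31.3 to -26.0). Of 604 pairs of a named gene and a group, 42 (6.95%) had 1 array far from the other 3, where chance alone gives about 1 in 20.

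On wild-type AML1-ETO9a replicate 4 these were Ccl12 (8.85), Epx (6.15), Gal (5.46), Lat2 (11.71), Prg2 (11.87), Prg3 (5.05), Septin5 (5.94), Socs3 (11.46), Tfrc (12.73), Tph1 (8.19) and Traf1 (7.75). On Booreana control replicate 2 they were Gp5 (9.45), Myc (4.88), Pf4 (12.27), Pmvk (10.002), Saa3 (6.08) and Tnfrsf1a (5.16). Booreana control replicate 1 stood apart in Bex4 (11.50) and Zfpm1 (13.42), replicate 3 in Csf3r (9.07), Ifitm1 (13.31) and Vldlr (8.02), and replicate 4 in Col4a1 (6.61) and Prss34 (14.31). Among Booreana AML1-ETO9a arrays, replicate 1 stood apart in Casp9 (9.33), replicate 2 in Ep300 (9.59) and replicate 4 in Lat2 (13.38) and Mpo (5.09). Of the other wild-type AML1-ETO9a arrays, replicate 1 did so in Gpx3 (10.82) and Mllt3 (7.06), replicate 2 in Adgre1 (12.45) and Gask1b (7.99), and replicate 3 in Cd14 (11.90). Of the wild-type controls, replicate 1 stood apart in Ciita (6.06) and Csf3r (10.05), replicate 2 in Hoxa9 (4.79), replicate 3 in Icam1 (8.73), and replicate 4 in Gask1b (7.03), Hba-a1 (8.95), Ifitm6 (12.13), Igfbp7 (9.76) and Tmc7 (9.34).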

How the results depend on the processing

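The tests with the animal number as a random effect (correlation 0.350), without 4 arrays and with a covariate were chosen after the data were seen. For AML1-ETO9a in wild-type cells, 551 probes became 336 without normalization between arrays, 1125 with array weights, 959 with the replicate block, 1062 with the random effect and 989 with the first component of the deviations as a covariate. In Booreana cells, 210 became 113 among probes detected on all arrays, 63 with only the 8 arrays compared, 532 with weights, 453 with the block, 661 with the random effect and 898 with the covariate. Between genotypes with the control vector, 810 became 535 among probes detected on all arrays, 516 with only the 8 arrays, 1289 with weights and 1843 with the covariate. With AML1-ETO9a, 477 became 252 among probes detected on all arrays, 739 with weights and 773 with the covariate. For the difference, 11 became 21 without background correction, 19 with an offset of 50, 6 without normalization, 6 with median scaling, 28 with the authors' values, 3 among probes detected on all arrays, 17 with 1 value per gene, 59 with weights, 37 with the block, 86 with the random effect, 7 without the 4 arrays highest on component 1 and 345 with the covariate. The stricter filter and 1 value per gene test fewer probes, only 8 arrays leave fewer samples for the spread, and the covariate comes from the same residuals, so it lowers the spread by construction. For the other changes the cause was not tested. Counts under the remaining alternatives lay within 1.5 times of these.

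Leaving out 1 array gave 355 (wild-type control replicate 3) to 770 (Booreana control replicate 2) probes with AML1-ETO9a in wild-type cells and 139 to 228 (Booreana control replicates 3 and 4) in Booreana cells. Between genotypes it gave 566 to 827 with the control vector and 319 to 624 with AML1-ETO9a. For the difference it gave 6 (wild-type AML1-ETO9a replicate 2), 7 (Booreana control replicate 1 or wild-type control replicate 3) and up to 14. The size of the Booreana response, 0.555, was 0.466 to 0.658 (Booreana control replicates 3 and 2), and 0.475 to 0.645 under other settings.

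Of 227 calls of named genes, 51 ended without at least 1 array. Reversed were Casp9 by its other probe, at 1.00 with the control vector and 1.24 with AML1-ETO9a, and Cd40 by another probe, at -0.16 with AML1-ETO9a; the cause was not tested. With the replicate block Prg2 (adjusted p = 0.0611) and Col4a1 (0.0528) in wild-type cells, Aen (0.0519) in Booreana cells, Sesn1 (0.0705) between controls, and Cxcl2 (0.067), Tnf (0.0733) and Csf2rb2 (0.0536) between genotypes with AML1-ETO9a were no longer called. Besides these and the changes given beside their results, the block changed no other call of a named gene or list. Between genotypes the block joined equal numbers that were not found to pair. Of 43 list calls, 21 stayed without normalization, 34 without the detection filter, and 42 each without background correction and with the authors' values. A block for the chip was not run, since the files name no chips. Near the background changes are compressed, and a fall from an undetected level could not be measured.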

Other observations

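The test of the genes around Myb was chosen after the values were seen.

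Single genes changed further with AML1-ETO9a, and no claim is made for their lists. In wild-type cells the death receptor Fas rose by 1.18 ± 0.20 (adjusted p = 0.00174, other probe 0.57, not past the threshold) and Slc7a11, a cystine transporter, by 1.44 ± 0.26 (adjusted p = 0.00351), while Slc2a3, a glucose transporter, fell by 1.00 ± 0.20 (adjusted p = 0.00802, and 0.12 without normalization between arrays). Hdc, which makes histamine, rose by 1.21 ± 0.23 (adjusted p = 0.00465), whereas Mcpt8 and Prss34 of the same mast cell and basophil list fell. In Booreana cells the platelet receptor Treml1 rose by 2.98 ± 0.61 (adjusted p = 0.018), a call that ended without Booreana AML1-ETO9a replicate 4 or control replicate 1 or 3 (up to 0.0625). Cpa3, a mast cell protease, rose by 2.38 ± 0.51 (adjusted p = 0.0256, other probes 3.25 and 2.03, the last not past the threshold), and its call ended without Booreana replicate 1 of either vector, AML1-ETO9a replicate 4 or control replicate 3 (up to 0.0893).

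Single genes also differed between genotypes. In control cells Klrd1, a receptor of NK cells, was higher by 2.04 ± 0.35 (adjusted p = 0.00141), Traf1 by 2.33 ± 0.32 and Cd40 by 2.19 ± 0.38 (other probes 0.72, 1.05 and 0.88, the last not past the threshold). Tnfrsf1a, a receptor for tumour necrosis factor, was at -1.83 ± 0.47 (adjusted p = 0.0275, other probes -1.72 and -1.70), and its call ended without any of the 4 wild-type controls (up to 0.0832). Without Booreana control replicate 2 it was at -1.16 (adjusted p = 0.00558). With AML1-ETO9a, Slc2a3 was higher in Booreana cells (1.49 ± 0.20, adjusted p = 0.000375).

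Casp9 was uneven among the Booreana arrays. Replicate 1 read 9.71 with the control vector and 9.33 with AML1-ETO9a, the other 6 between 5.04 and 6.12, and the 8 wild-type arrays between 10.28 and 10.74.

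Genes beside Myb differed between genotypes, which may reflect a stretch of chromosome that differs between the strains. Ahi1, the nearest tested gene on 1 side, was higher in Booreana cells (3.09 ± 0.23 with the control vector, adjusted p = 6.68e-07, and 1.94 ± 0.23 with AML1-ETO9a, adjusted p = 9.58e-05). Sgk1 was lower with the control vector (-0.95 ± 0.19, adjusted p = 0.00534). Slc35d3 was higher with AML1-ETO9a (1.59 ± 0.36, adjusted p = 0.0197), a call that ended without any of 4 single arrays (up to 0.0742). These genes lie outside the rule for named genes and were chosen after their values were seen. Of the 40 tested genes nearest to Myb, 6 were called between genotypes, against a median of 3 and a highest value of 12 over 8026 windows of that size. That was more than in 85.0% of windows, below the 95% the explanation needed and above the median, so it stays open.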
